A study of Mus musculus with 9 samples.

How the data were processed

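Gene expression was measured by RNA sequencing in 9 brain libraries of KM mice labelled male, 3 each from young mice given saline, aged mice given saline and aged mice given GRP-E1F2. Per the labels' protocols, libraries were made from 0.4 ug of total RNA with the NEBNext Ultra II kit, from fragmented mRNA and random primers. The extraction protocol in the labels speaks of retina, while tissue and source are labelled brain, so marker lists for retinal cells were fixed along with those for brain. Per the submitters' processing notes, HISAT2, Picard, SAMtools 0.1.18 and GATK were used with the genome build mm10. The values in the deposited table are TPM, which the authors computed per gene and library. The tool that made them, its annotation and its handling of strand and of reads that match several genes are not given in the sources used here. Reads shared between near-identical genes could therefore have been split in an unknown way.

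The table lists 22192 genes, of which 3809 were at 0 in every library. Library sums lay between 999667 and 999929 TPM. TPM keeps no record of depth, so the depth per library is unknown and no counting error could be given. A value of 0 means only that a gene is listed at 0. Gene symbols were used as the table gives them, and positions were taken from a RefSeq gene table of the GRCm38.p6 assembly, the build also called mm10, which held 20545 of the genes. Of 759 symbols in the fixed lists 752 were found, some through older names. The 7 not found were Fcrls, Mx1, Arntl, Hbb-b1, Hbb-b2, Ighm and Igkc, which were not analysed here.

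TPM values were transformed to log2(TPM + 1), and 13301 genes with a mean of at least 1 TPM over the 9 libraries were tested. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend) over all 9 libraries, which share 1 estimate of the spread per gene. The contrasts were aged saline minus young saline, aged GRP-E1F2 minus aged saline, and aged GRP-E1F2 minus young saline, with an F-test over the 3 groups. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are said to have risen or fallen. For Pdyn an exact permutation test of its 3 against 3 values was added. That test treats the 3 libraries of a group as separate, which the real libraries described below may not be. Of 49 gene lists fixed in advance, 25 of pathways and 24 of cell types and regions, the 46 with at least 4 tested genes were tested with camera at a preset correlation of 0.01. Camera asks whether a list moved against all other genes, and its p-values were adjusted over the lists within a comparison. Each list was also tested with an estimated correlation and with fry, and its genes were adjusted over the list alone. None of the list calls held with an estimated correlation.

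Genes were named by a rule set in advance. It took Pdyn, Penk, Pomc, Pnoc and Oprk1, the 8 largest rises and 8 largest falls per comparison among called genes whose groups did not overlap, and up to 4 genes per list with the smallest p. It also took up to 3 genes with the highest mean TPM per marker list, and the 8 largest age changes among genes that moved back. Predicted genes and pseudogenes were left out of the rule. A few genes that the rule took are not reported here. Ddx3y, Eif2s3y, Kdm5d, Uty, Ddx3x, Eif2s3x, the other Hox genes, Gdf10, Hopx, Tfap2a, Tfap2b, En1, Pde6b, Gnat1, Pdc, Cnga1, Gm14037 and Gm54192 fall outside it and were chosen after their values were seen.

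The test was first tried on simulated data with 13301 genes and 3 libraries per group. In the simulated comparison of GRP-E1F2 with aged saline it recovered 95 of 100 genes changed by 1 on the log2 scale and 69 of 100 changed by 0.5, with 8 false calls. It made no calls in the unchanged age comparison. The simulated libraries were independent and their noise was drawn separately for each gene, unlike the real libraries described below. The trial therefore does not give the error rate in the real data. Values for an unchanged treated group that shares the aged libraries were simulated 100 times. Alternatives tried were pseudocounts of 0.1 and 5 TPM, no filter and a mean of at least 5 TPM, median-of-ratios scaling and quantile normalisation, leaving out mitochondrially encoded genes, the replicate number as a block, fits of only the groups compared, robust and untrended eBayes, array weights, a minimum log2 fold change of 1, and leaving out each library. A fit of 2 libraries per group, and leaving out a library of the group outside a comparison, were added after the data were seen. Tests on counts were not run because the table holds none. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.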

Results

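RNA from the brains of KM mice, an outbred stock, labelled male, was measured in 9 libraries. Young mice of 5 months and aged mice of 18 months had received saline by gavage, and further aged mice had received 200 mg/kg of GRP-E1F2, a polysaccharide fraction of ginseng root, every 2 days for 4 weeks. Each group held 3 libraries, which the labels call parallel samples. Nothing in the labels says that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. The deposited table gives TPM values for 22192 genes and no counts, so the depth is unknown. Between 16715 and 16962 genes were above 0 in a library, and the 10 highest genes took 7.87% to 9.94% of its TPM. Values below are means ± SD over the libraries of a group (n = 3). Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes.

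In each group, 1 library lay between the other pair at nearly every gene. Young library 3, aged library 2 and treated library 3 did so at 95.3%, 96.1% and 96.0% of the genes that differed at least 1.3-fold between the other pair. Chance gives 33.3%, while arrangements across groups reached up to 90.9%. In the other 6 arrangements within a group the share was at most 23.8%. It was held low in part because only 1 of 3 libraries can lie between at a gene. Of the genes listed at 0 in both other libraries, 0.221%, 0.566% and 1.40% were above 0 in these 3 libraries, against 14.7% to 17.6% in the other arrangements within a group. The SDs and p-values over 3 libraries are therefore likely smaller than those of 3 separate samples would be. The count of all genes changed in a comparison is also given from 2 libraries per group, without these 3 libraries, a setting chosen after seeing the data. Counts within gene lists are from 3 libraries unless stated.

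**Figure D1:**
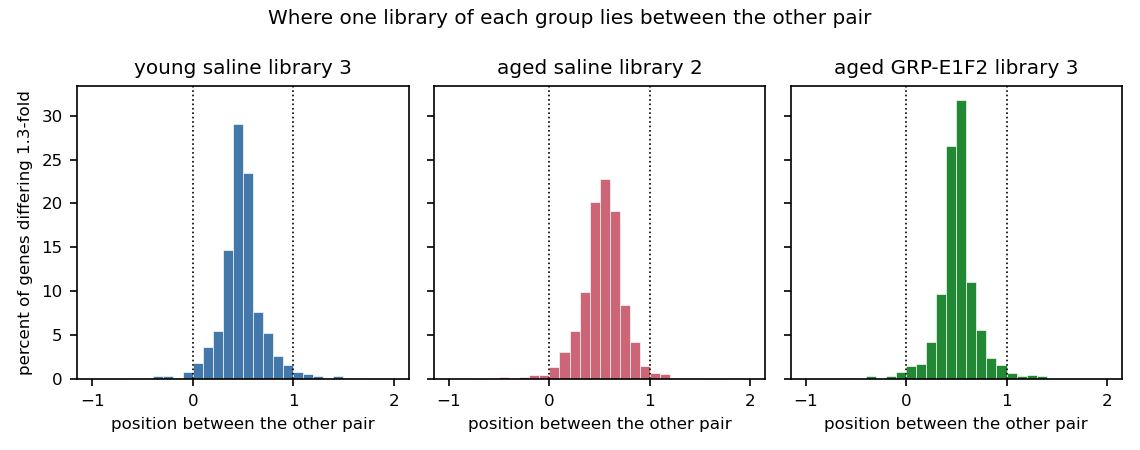
Position of young library 3, aged library 2 and treated library 3 between the other pair of their group, for each gene that differed at least 1.3-fold between that pair (x axis: 0 and 1 are the other pair, on the TPM scale; y axis: percent of those genes). In the 3 panels, 95.3%, 96.1% and 96.0% of the genes lie between 0 and 1, most of them near the middle.

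Marker genes of brain regions differed between groups and between libraries of a group. Genes of cerebellar neurons had a mean log2(TPM + 1) of 7.26 to 7.76 in the young libraries, 6.70 to 6.83 in the aged and 2.73 to 2.80 in the treated libraries. Genes of striatal projection neurons stood at 2.82 in young library 2 and at 5.15 in young library 1. Drd1, the D1 dopamine receptor of striatal neurons, was 0.802 TPM in young library 2 against 10.2 TPM in young library 1. Ttr, the transthyretin gene made in the choroid plexus, ran from 155 to 1241 TPM among the aged and from 15.6 to 951 TPM among the treated libraries. The pituitary hormone genes Gh and Prl were 263 and 554 TPM in treated library 2, while treated library 1 had Gh listed at 0 and Prl at 0.36 TPM. The extraction protocol speaks of retina while the tissue is labelled brain. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at most 0.174 TPM, although the mice are labelled male, while the X-linked copies Ddx3x and Eif2s3x were 38.8 to 71.5 TPM. These values do not bear out the labelled sex, but how reads that match both X and Y copies were handled is not given in the sources used here.

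**Figure D2:**
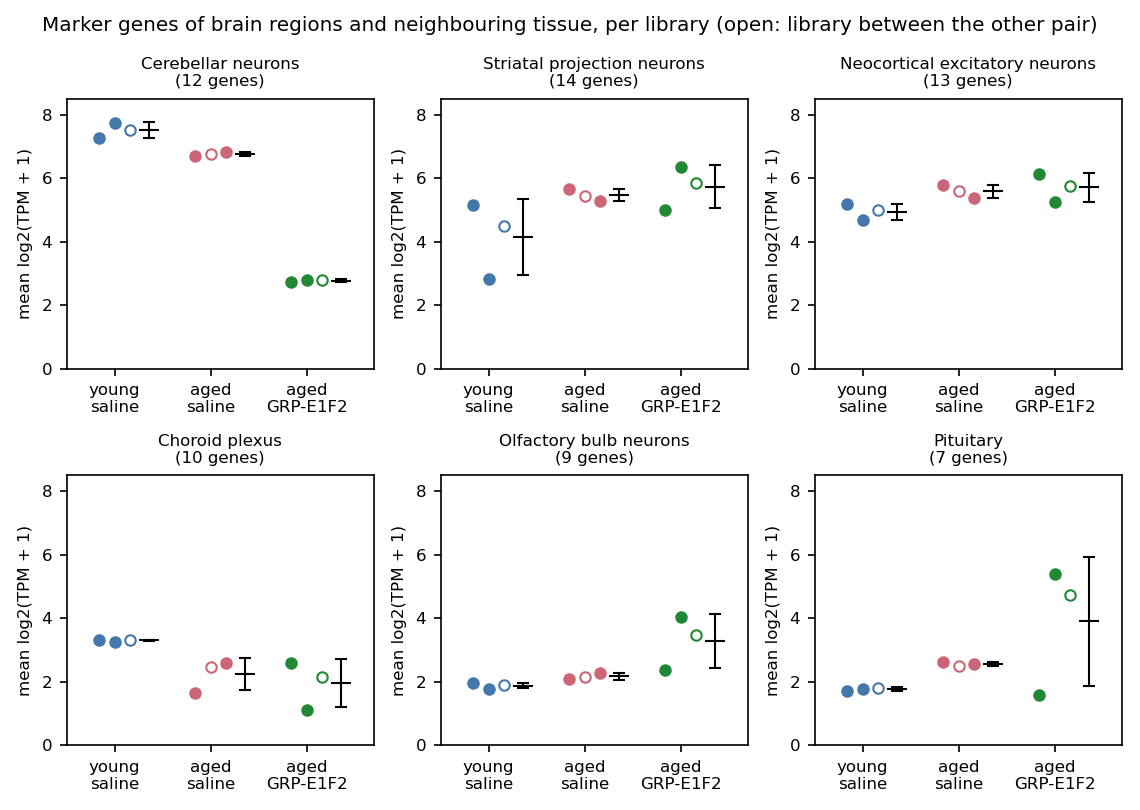
Mean log2(TPM + 1) of the genes of 6 marker lists in each library (points; open points are young library 3, aged library 2 and treated library 3), with the group mean and SD beside them (bars, n = 3). Cerebellar genes lie at 2.73 to 2.80 in the treated libraries and at 6.70 or above in all others, and striatal genes lie at 2.82 in young library 2.

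The first comparison asked what differed between aged and young brains under saline. Of the myelin genes 12 of 15 fell with age, such as Mbp, myelin basic protein, from 4269 ± 62.8 to 3130.0 ± 150.5 TPM (log2 fold change -0.45, adjusted p = 0.0036). Of the immediate early genes, which neuronal activity induces, 7 of 18 rose, with Egr1 at 58.6 ± 12.4 TPM in young and 119 ± 20.7 TPM in aged libraries. Astrocyte and cerebellar genes fell at 10 of 12 and 10 of 12, and genes of homeostatic microglia rose at 6 of 11. None of the calls of these lists held with an estimated correlation. In all, 2217 of 13301 genes passed an adjusted p of 0.05, 729 of which rose and 1488 fell. Scaling the libraries by median of ratios gave 922 that rose and 1014 that fell, and quantile normalisation gave 966 and 1102. Of 14 tested genes of hindbrain patterning and other hindbrain and cerebellar cells, a list made after the result was seen, 9 fell (median -1.72). A difference in the tissue taken could thus not be told apart from age in these changes.

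Pdyn encodes prodynorphin, the precursor of the dynorphin opioid peptides, and is the gene named in the title of the series (NCBI gene 18610, chromosome 2, 129686549 to 129699938, mm10). It rose from 9.99 ± 6.75 TPM in young to 28.1 ± 3.57 TPM in aged libraries (log2 fold change 1.63, SE 0.447, adjusted p = 0.0392). An exact two-sided permutation test of the same values gave p = 0.1, the smallest that 3 against 3 libraries allow. It treats all 3 libraries of a group as separate, which young library 3 and aged library 2 may not be. Oprd1, the delta opioid receptor, rose from 1.34 ± 0.427 to 3.19 ± 0.392 TPM (adjusted p = 0.0083). These were the 2 of 8 opioid genes that passed, and 2 did so when adjusted over the list alone. Penk, the proenkephalin gene, was 228 ± 88.1 and 345 ± 31.2 TPM (adjusted p = 0.254), Oprk1, the kappa receptor to which dynorphin binds, 1.18 ± 0.830 and 1.60 ± 0.196 TPM (0.406), Pnoc 19.0 ± 1.25 and 14.6 ± 5.30 TPM (0.189), and Pomc 3.05 ± 0.158 and 3.91 ± 0.720 TPM (0.588). The opioid list as a whole was not called (adjusted p = 0.184). In the fit of 2 libraries per group Pdyn had a log2 fold change of 1.78 and an adjusted p of 0.412. Over all alternatives the adjusted p of Pdyn with age ran from 6.63e-08, with array weights, to 0.412. Beside this, the median log2 fold change of 14 striatal genes, a region where Pdyn is abundant, was 1.25.

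**Figure D3:**
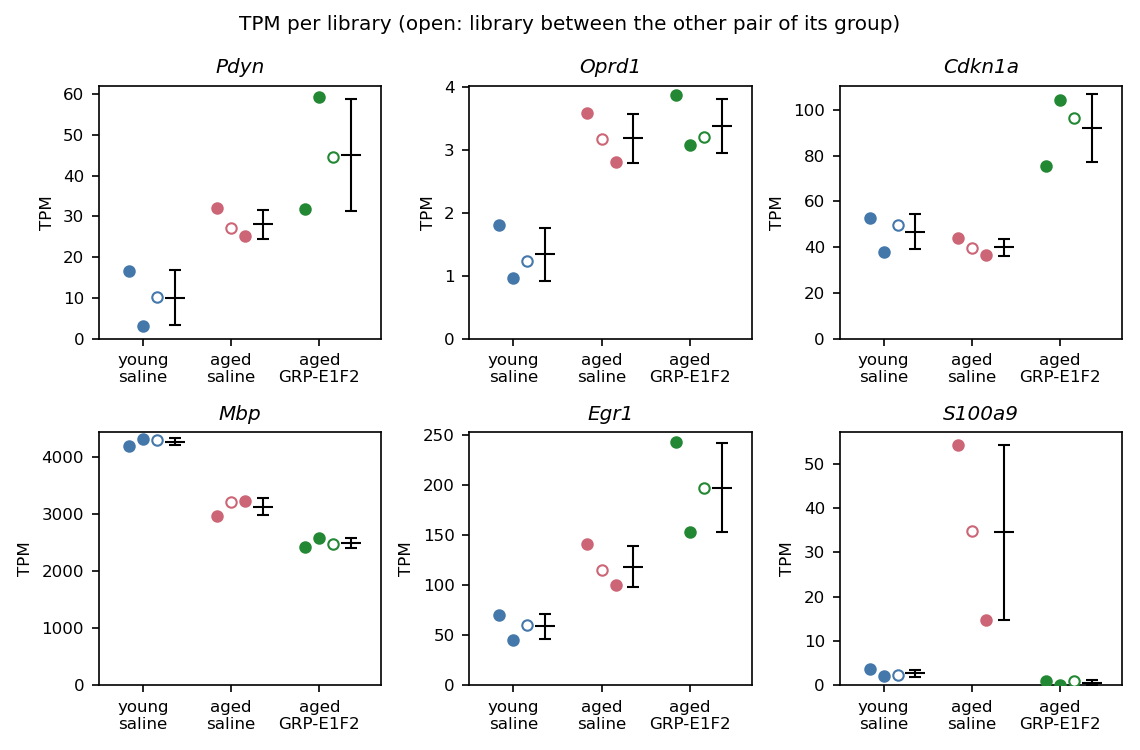
TPM of 6 genes in each library of young saline, aged saline and aged GRP-E1F2 mice (points; open points are young library 3, aged library 2 and treated library 3), with the group mean and SD beside them (n = 3). Pdyn runs from 3.18 to 16.7 TPM in young, 25.2 to 32.1 TPM in aged and 31.8 to 59.3 TPM in treated libraries.

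With 2 libraries per group no gene of any list passed with age, while camera at the preset correlation called 15 lists, against 16 with 3 libraries. Of the 15 genes of mature oligodendrocytes and myelin, 12 fell, none rose, and 14 fell when adjusted over the list alone (camera adjusted p = 2.85e-07, and adjusted p = 0.732 with an estimated correlation). Of 12 astrocyte genes 10 fell, among them Aqp4, the water channel of astrocyte endfeet, from 43.7 ± 6.78 to 21.8 ± 0.906 TPM, and Gjb6, connexin 30, from 107 ± 5.32 to 56.7 ± 4.22 TPM. Adjusted over the list alone, 10 fell and 1 rose (camera 1.94e-05, adjusted p = 0.732 with an estimated correlation). Of 13 genes of meningeal and perivascular fibroblasts 11 fell, 12 adjusted over the list alone, with the proteoglycan Dcn at 33.6 ± 4.97 and 11.6 ± 1.51 TPM (camera 6e-07, adjusted p = 0.732 with an estimated correlation). The cerebellar list lost 10 of 12, or 12 adjusted over the list alone, such as Car8 of Purkinje cells, from 457 ± 88.9 to 237 ± 23.2 TPM, and Gabra6 of granule cells, from 182 ± 37.1 to 97.0 ± 4.92 TPM (camera 2.06e-06, adjusted p = 0.732 with an estimated correlation). Choroid plexus genes fell at 6 of 10, and 7 fell and 1 rose adjusted over the list alone (camera 0.0162, adjusted p = 0.732 with an estimated correlation). Of 15 genes of the glucocorticoid response 5 fell, 7 adjusted over the list alone, led by the metallothionein Mt1 at 8494 ± 725 and 4764 ± 827 TPM (camera 0.0251, adjusted p = 0.732 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had a median change of -0.14, with 5 of 33 falling, 13 adjusted over the list alone, such as Sdha from 212 ± 3.99 to 182 ± 3.37 TPM (camera 0.000291, adjusted p = 0.732 with an estimated correlation).

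Among immediate early genes 7 of 18 rose and 13 did so adjusted over the list alone, including the nuclear receptor Nr4a1 from 33.0 ± 3.99 to 69.6 ± 11.4 TPM and Junb from 51.1 ± 9.74 to 90.1 ± 12.1 TPM (camera 2.54e-06, adjusted p = 0.732 with an estimated correlation). Of 11 genes of homeostatic microglia 6 rose, 8 adjusted over the list alone. Csf1r, the receptor on which microglia depend, went from 15.1 ± 1.46 to 19.5 ± 0.671 TPM and the purine receptor P2ry13 from 2.30 ± 0.246 to 4.12 ± 0.621 TPM (camera 1.17e-05, adjusted p = 0.732 with an estimated correlation). Neocortical genes rose at 5 of 13, 9 adjusted over the list alone, with the transcription factors Mef2c at 20.8 ± 5.58 and 45.3 ± 8.90 TPM and Tbr1 at 8.09 ± 4.04 and 21.8 ± 3.53 TPM (camera 3.65e-05, adjusted p = 0.732 with an estimated correlation). In the list of the postsynaptic density 5 of 20 genes rose and 1 fell, 9 and 1 adjusted over the list alone. The kinase Camk2a went from 327 ± 96.8 to 633 ± 73.0 TPM, while the glutamate receptor subunit Gria4 fell from 54.4 ± 5.75 to 37.9 ± 3.39 TPM (camera 6.25e-05, adjusted p = 0.732 with an estimated correlation). The striatal list was called upward although none of its 14 genes passed, nor did any adjusted over the list alone (camera 1.16e-05, adjusted p = 0.732 with an estimated correlation). Dopamine receptor and cAMP genes were also called upward, with 1 of 15 rising and 1 falling, likewise adjusted over the list alone (camera 0.00065, adjusted p = 0.732 with an estimated correlation).

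Mitochondrially encoded genes rose at 3 of 13, 5 adjusted over the list alone (camera 1.17e-05, adjusted p = 0.732 with an estimated correlation). Antigen presentation genes had 1 of 14 rising and none adjusted over the list alone (camera 0.0136, adjusted p = 0.759 with an estimated correlation). The list of cytosolic ribosomal proteins was called upward (camera 0.0196, adjusted p = 0.759 with an estimated correlation), with a median of 0.07 but a mean of -0.02. Of 41 genes 1, Rps2, rose and 2 fell, among them Rpl30 from 945 ± 3.46 to 331 ± 206 TPM, likewise adjusted over the list alone. The ribosomal call ended under quantile normalisation. Of the 12 senescence cell-cycle inhibitors and markers none passed, nor did any adjusted over the list alone (camera 0.749, upward against other genes, with a median of -0.05). Cdkn1a, the cell-cycle inhibitor p21, was 46.7 ± 7.68 TPM in young and 39.9 ± 3.70 TPM in aged libraries (adjusted p = 0.335). Among 16 senescence-associated secretory factors 2 rose and 4 fell, 2 and 7 adjusted over the list alone (camera 0.236, and downward by fry at an adjusted p of 0.0478). Genes of disease-associated microglia rose at 3 and fell at 2 of 19, 6 and 3 adjusted over the list alone (camera 0.184, upward, with a mean of 0.11 and a median just under 0).

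Among called genes whose groups did not overlap, predicted genes left out, the largest rises with age were S100a5, from 0.630 ± 0.0146 to 38.9 ± 19.2 TPM (log2 fold change 4.47, adjusted p = 0.00773), and Omp, the olfactory marker protein, from 1.02 ± 0.372 to 23.2 ± 7.30 TPM (3.55, adjusted p = 0.00268). S100a8 and S100a9, subunits of the calprotectin of neutrophils, rose from 1.84 ± 1.02 to 21.4 ± 7.98 and from 2.63 ± 0.782 to 34.6 ± 19.8 TPM. Ngp, a neutrophil granule gene, rose from 0.716 ± 0.1 to 6.18 ± 2.25 TPM. The chemokine gene Ccl21a was listed at 0 in all young libraries and at 3.01 ± 0.557 TPM in the aged. Rpl39l fell from 55.1 ± 11.8 to 1.39 ± 1.20 TPM (log2 fold change -4.70, adjusted p = 0.00148), but it is a near copy of Rpl39 and reads could have been split between them. Hox genes, which mark the hindbrain and spinal cord, followed, with Hoxb5 falling from 12.2 ± 1.37 to 0.746 TPM, Hoxc4 from 9.42 ± 0.410 to 0.790 ± 0.810 TPM and Hoxa5 from 8.47 ± 1.86 to 0.782 ± 0.754 TPM. Slc6a5, the transporter of glycinergic neurons, fell from 9.58 ± 2.90 to 1.58 ± 0.151 TPM. Nps, the neuropeptide S gene of brainstem neurons, fell from 5.10 ± 1.11 TPM to a listed 0 in every aged library (adjusted p = 4.23e-05).

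Groups did not overlap at 5517 genes (41.5%, where chance gives 10% for 3 separate libraries per group), and with 2 libraries per group at 6101 genes (45.9%, chance 33.3%). With 2 libraries per group 3 genes passed, Nps (adjusted p = 0.025) and the predicted genes Gm14037 and Gm54192, while 1431 had an unadjusted p under 0.05. All 2217 genes kept their sign, which is nearly fixed where the library left out lies between the other pair. Leaving out 1 library at a time gave 371 to 2635 genes (635 without young library 2, 371 without young library 3, 1330 without aged library 1, 379 without aged library 2 and 1172 without treated library 3) and ended the Pdyn call without young library 2 or 3, any 1 aged library or treated library 3.

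The second comparison asked what differed between aged mice given GRP-E1F2 and aged mice given saline. All 12 genes of cerebellar neurons fell with GRP-E1F2: Pcp2, a Purkinje cell gene (NCBI gene 18545, chromosome 8, 3623369 to 3625547, mm10), went from 807 ± 163 to 5.99 ± 2.97 TPM (log2 fold change -6.92, SE 0.296, adjusted p = 1.61e-06). Cbln3, a granule cell gene, went from 276 ± 2.13 to 0.190 ± 0.132 TPM (-7.87, SE 0.119, adjusted p = 2.1e-09). Of the genes of olfactory bulb neurons 5 of 9 rose, of those of neurogenesis 7 of 12 and of those of homeostatic microglia 5 of 11, while 7 of 15 myelin and 6 of 12 astrocyte genes fell. None of the calls of these lists held with an estimated correlation. Pdyn, the gene that the title says was inhibited, was 28.1 ± 3.57 TPM with saline and 45.2 ± 13.8 TPM with GRP-E1F2 (log2 fold change 0.63, SE 0.447, adjusted p = 0.353). An exact two-sided permutation test of Pdyn gave p = 0.2, where 0.1 is the smallest possible. In all, 2771 genes passed, 994 of which rose and 1777 fell, and quantile normalisation gave 1466 and 1470. A lower yield of cerebellum in the treated samples, weighed further below, may account for the cerebellar falls. Since TPM values are shares of a library, other lists could then shift too. Their changes could thus not be ascribed to GRP-E1F2 alone.

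All 12 cerebellar genes fell, with a median of -3.70, and all did adjusted over the list alone (camera adjusted p = 2.3e-19, and adjusted p = 0.288 with an estimated correlation). All 12 passed with 2 libraries per group as well, Cbln3 at -7.95 (adjusted p = 1.13e-05) and Pcp2 at -6.90 (0.000995). Of the other lists called with GRP-E1F2, 2 astrocyte, 2 thalamic genes and 1 neurogenesis gene fell and 1 neurogenesis gene rose with 2 libraries per group, and no gene of the remaining lists passed. Gabra6 fell from 97.0 ± 4.92 to 1.35 ± 0.403 TPM, Car8 from 237 ± 23.2 to 5.83 ± 0.247 TPM and Cbln1 from 359.6 ± 19.1 to 12.7 ± 2.79 TPM. En2, a transcription factor of the midbrain and hindbrain border, fell from 32.9 ± 2.82 to 0.428 ± 0.142 TPM. Thalamic genes fell at 5 of 11, 6 adjusted over the list alone, among them Rora, from 10.2 ± 2.64 to 2.18 ± 0.713 TPM and also expressed in Purkinje cells, and Prkcd, from 31.6 ± 15.0 to 9.32 ± 4.16 TPM (camera 0.024, adjusted p = 0.836 with an estimated correlation). Parvalbumin, Pvalb, a calcium-binding protein of fast-spiking interneurons and Purkinje cells, fell from 1944 ± 62.0 to 356 ± 45.3 TPM.

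Of 12 genes of neurogenesis and proliferation 7 rose and 1 fell, 9 and 1 adjusted over the list alone. Dlx1 and Dlx2, transcription factors of the interneuron lineage, rose from 13.9 ± 0.332 to 41.0 ± 5.16 TPM and from 4.18 ± 0.317 to 12 ± 3.07 TPM, and Igfbpl1, a gene of newborn neurons, from 0.323 ± 0.16 to 4.39 ± 0.434 TPM. Neurod1, which cerebellar granule cells also express, fell from 84.1 ± 2.10 to 4.70 ± 0.863 TPM (camera 0.00107, adjusted p = 0.715 with an estimated correlation). Olfactory bulb genes rose at 5 of 9, the same number adjusted over the list alone, including the calcium sensor Scgn, from 0.785 ± 0.0939 to 8.84 ± 5.02 TPM, and Sp8, from 0.586 ± 0.175 to 5.09 ± 2.53 TPM (camera 0.00262, adjusted p = 0.836 with an estimated correlation). Their mean log2(TPM + 1) was 2.36 in treated library 1 and 4.04 in treated library 2. Of 11 microglial genes 5 rose, 9 adjusted over the list alone, with the fractalkine receptor Cx3cr1 at 10.4 ± 0.579 and 15.2 ± 2.04 TPM and Sall1 at 3.13 ± 0.212 and 6.64 ± 1.91 TPM (camera 0.000732, adjusted p = 0.836 with an estimated correlation). Cholesterol synthesis genes rose at 5 of 18, 6 adjusted over the list alone, such as squalene epoxidase, Sqle, from 18.4 ± 1.08 to 23.5 ± 2.89 TPM (camera 0.003, adjusted p = 0.836 with an estimated correlation).

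Myelin genes fell at 7 of 15, 8 adjusted over the list alone, with Mbp at 3130.0 ± 150.5 and 2495 ± 84.2 TPM (camera 0.00107, adjusted p = 0.836 with an estimated correlation). Astrocyte genes fell at 6 of 12, 7 adjusted over the list alone. Aldoc, an aldolase of astrocytes and Purkinje cells, went from 1144 ± 78.7 to 606 ± 3.43 TPM and Aqp4 from 21.8 ± 0.906 to 11 ± 1.13 TPM (camera 0.00998, adjusted p = 0.836 with an estimated correlation). Reactive astrocyte genes fell at 5 of 13, 6 adjusted over the list alone, including the intermediate filament genes Gfap, from 71.6 ± 22 to 41.7 ± 4.58 TPM, and Vim, from 48.1 ± 6.16 to 28.0 ± 1.08 TPM (camera 0.0171, adjusted p = 0.715 with an estimated correlation). Mitochondrially encoded genes fell at 3 of 13, 4 adjusted over the list alone (camera 0.0171, adjusted p = 0.892 with an estimated correlation). Immediate early genes were called upward, with 5 of 18 rising and 3 falling, 8 and 3 adjusted over the list alone (camera 0.024, adjusted p = 0.892 with an estimated correlation). Fosl2 rose from 9.43 ± 0.835 to 22.2 ± 5.67 TPM and Fosb from 7.42 ± 1.09 to 15.1 ± 3.94 TPM, while Ier2 fell from 24.4 ± 0.429 to 17.8 ± 1.41 TPM. In the postsynaptic list 4 of 20 rose and 1, Gria4, fell, likewise adjusted over the list alone (camera 0.0295, adjusted p = 0.92 with an estimated correlation). The calls of the immediate early and postsynaptic lists ended under quantile normalisation.

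The opioid list was called upward with GRP-E1F2 (camera 0.0329, adjusted p = 0.836 with an estimated correlation), a call that ended under median-of-ratios scaling and quantile normalisation. Its mean log2(TPM + 1) was 3.44 to 3.51 in the aged libraries and 3.59, 4.12 and 3.96 in treated libraries 1, 2 and 3, where the pituitary list stood at 1.59, 5.399 and 4.73 and the striatal list at 5.01, 6.35 and 5.85. Of its 8 genes 2 rose, also adjusted over the list alone. These were Oprm1, the mu opioid receptor, from 0.711 ± 0.414 to 2.34 ± 0.203 TPM (adjusted p = 0.00343), and Oprl1, the nociceptin receptor, from 15.8 ± 1.60 to 20.9 ± 1.18 TPM (0.0111). Penk was 345 ± 31.2 and 459 ± 231 TPM (adjusted p = 0.66), Pomc 3.91 ± 0.720 and 6.41 ± 3.47 TPM (0.316), Pnoc 14.6 ± 5.30 and 20.9 ± 0.804 TPM (0.0918) and Oprk1 1.60 ± 0.196 and 1.67 ± 0.537 TPM (0.961). Senescence cell-cycle inhibitors and markers were not called as a list (camera 0.995), with 1 of 12 rising and 1 falling, likewise adjusted over the list alone. Cdkn1a rose from 39.9 ± 3.70 to 92.1 ± 14.8 TPM (log2 fold change 1.18, SE 0.146, adjusted p = 0.000801, and 0.0617 with 2 libraries per group). Cdkn1b, the inhibitor p27, fell from 92.6 ± 6.27 to 46.7 ± 1.74 TPM (log2 fold change -0.97, adjusted p = 0.000153, and 0.0283 with 2 libraries per group). Among 16 secretory factors 2, Mmp2 and Timp2, rose and 3 fell, 2 and 4 adjusted over the list alone, with Vegfa going from 77.9 ± 7.75 to 49.8 ± 4.62 TPM (camera 0.692). Myd88, an adaptor of Toll-like receptors, fell from 5.50 ± 0.576 to 2.56 ± 0.487 TPM.

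**Figure D4:**
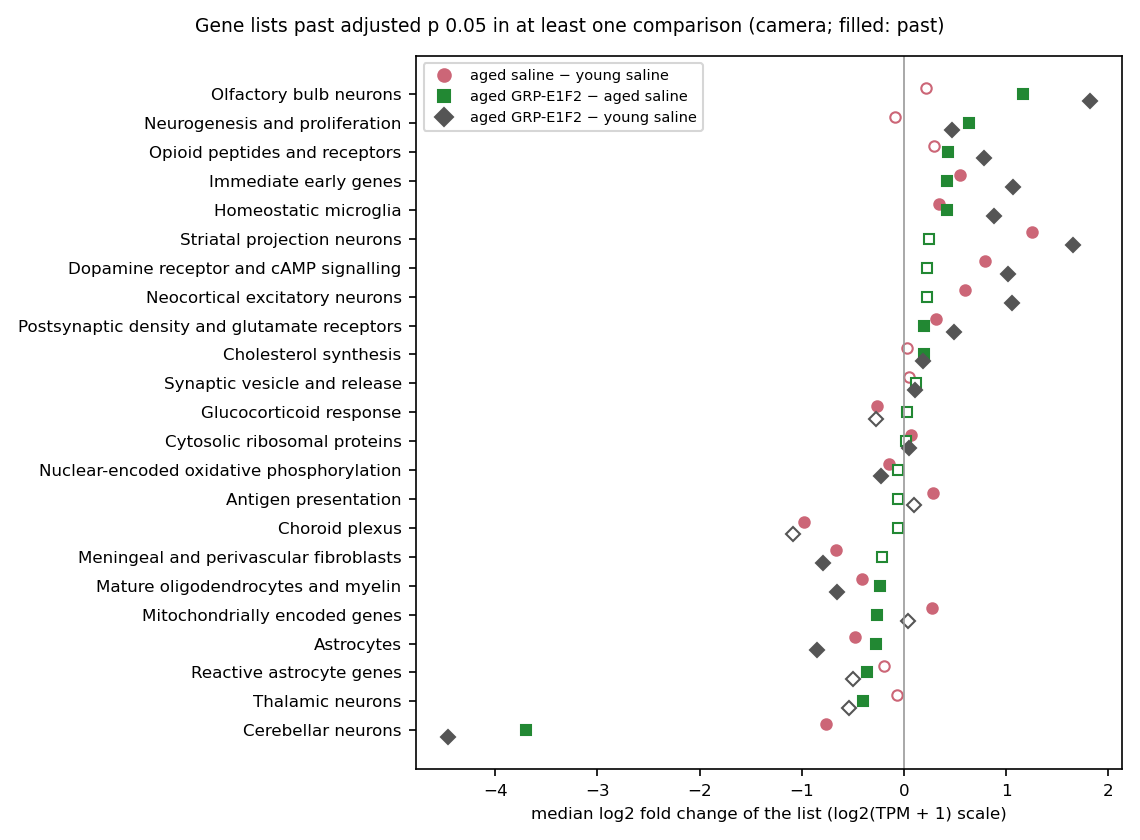
Median log2 fold change (log2(TPM + 1) scale) of the gene lists past an adjusted p of 0.05 in at least 1 comparison, for aged against young saline (circles), GRP-E1F2 against saline in aged mice (squares) and aged GRP-E1F2 against young saline (diamonds); filled symbols passed by camera with a preset correlation. Cerebellar neurons lie farthest from 0 after GRP-E1F2, at -3.70 against aged and -4.46 against young.

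Among called genes whose groups did not overlap, the largest rises with GRP-E1F2 were Rpl39l, from 1.39 ± 1.20 to 38.5 ± 18.4 TPM, Prm1 from 0.911 ± 1.58 to 8.62 ± 2.93 TPM, Scgn, Wfdc18 from 2.38 ± 2.10 to 11.6 ± 3.76 TPM, Igfbpl1, and Tmem273 from 0.633 ± 0.0655 to 5.52 ± 0.887 TPM. Igfbpl1 (adjusted p = 0.0104) and Tmem273 (0.00685) still passed with 2 libraries per group. Other large falls besides Cbln3 and Pcp2 were Cnpy1, from 124 ± 23.5 to 0.222 ± 0.385 TPM, and Ppp1r17, a Purkinje cell phosphatase inhibitor, from 65.1 ± 2.16 to 0.776 ± 0.264 TPM. Groups did not overlap at 4834 genes (36.3%, chance 10% for 3 separate libraries per group), and with 2 libraries per group at 5391 (40.5%, chance 33.3%). With 2 libraries per group 248 genes passed, 14 of which rose and 234 fell. All 2771 genes kept their sign, which the position of the libraries left out made nearly certain. Leaving out 1 library at a time gave 1345 to 3060 genes, with 1345 without aged library 2 and 1376 without treated library 3.

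The third comparison set aged mice given GRP-E1F2 against young mice given saline. Pdyn rose from 9.99 ± 6.75 to 45.2 ± 13.8 TPM (log2 fold change 2.26, SE 0.447, adjusted p = 0.00315; 0.0549 with 2 libraries per group), and its exact permutation p was 0.1, the smallest possible. The opioid list rose at 4 of 8 genes, the same number adjusted over the list alone: Pdyn, Oprm1 (0.907 to 2.34 TPM), Oprd1 (1.34 to 3.38 TPM) and Oprl1 (17.6 to 20.9 TPM). Its camera adjusted p was 0.00531, and adjusted p = 0.714 with an estimated correlation. Penk was 228 ± 88.1 and 459 ± 231 TPM (adjusted p = 0.0744). Beside this, the median log2 fold change of 14 striatal genes, a region where Pdyn is abundant, was 1.65 in the same comparison. Cerebellar genes fell at all 12, also adjusted over the list alone, with Cbln3 at -8.51 and Pcp2 at -7.90 (camera 7.4e-12, adjusted p = 0.64 with an estimated correlation). Myelin genes fell at 14 of 15, also adjusted over the list alone (camera 2.95e-06, adjusted p = 0.64 with an estimated correlation). Mbp stood at 4269 in young, 3130.0 in aged and 2495 TPM in treated libraries. A difference in the tissue taken could not be told apart from age or GRP-E1F2 in the changes of this comparison.

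Microglial genes rose at 10 of 11 (camera 2.95e-06), with Csf1r at 15.1 and 24.2 TPM, and immediate early genes rose at 13 and fell at 2 of 18 (camera 5.02e-05), with Egr1 at 58.6 and 198 TPM. Upward calls also went to postsynaptic genes (13 rose and 1 fell of 20, camera 9.99e-05), neocortical genes (10 and 2 of 13, 0.00151) and striatal genes (8 and 0 of 14, 0.000268). Dopamine receptor and cAMP genes (8 and 1 of 15, camera 0.00323), olfactory bulb genes (6 and 1 of 9, 0.0037) and neurogenesis genes (6 and 1 of 12, 0.0368) were called upward too. So were cholesterol synthesis genes (7 and 0 of 18, camera 0.00309) and synaptic vesicle genes (8 and 2 of 20, 0.0394). All of these lists had an adjusted p of 0.714 with an estimated correlation. Cytosolic ribosomal genes rose at 7 and fell at 1 of 41 (camera 0.0229, adjusted p = 0.733 with an estimated correlation). Astrocyte genes (1 rose and 11 fell of 12, camera 0.000201), meningeal fibroblast genes (1 and 12 of 13, 0.000659) and nuclear genes of oxidative phosphorylation (0 and 21 of 33, 0.00128) were called downward, each with an adjusted p = 0.714 with an estimated correlation.

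With 2 libraries per group all 12 cerebellar, 11 myelin, 8 astrocyte and 7 fibroblast genes fell, and 6 immediate early, 5 microglial, 5 olfactory bulb, 3 postsynaptic, 3 neocortical and 3 neurogenesis genes rose. At most 1 gene rose in each of the opioid, dopamine receptor, synaptic vesicle and ribosomal lists, and none passed in the striatal, cholesterol synthesis and oxidative phosphorylation lists. Adjusted over the list alone, the counts from 3 libraries of rises and falls differed only for striatal genes (14 rose), neocortical genes (11 rose), dopamine receptor genes (9 rose), ribosomal genes (6 rose) and oxidative phosphorylation (23 fell). The neurogenesis call ended under median-of-ratios scaling and quantile normalisation, and the ribosomal and synaptic vesicle calls ended under quantile normalisation. The pituitary hormone genes Gh and Prl were called higher than in young libraries (adjusted p = 0.0364 and 0.0349) and did not pass with 2 libraries per group (0.276 and 0.26). The call rested on treated library 2 and on the in-between treated library 3, at 137 and 280 TPM, which may not be separate from library 2. In all, 6204 genes passed, 2294 of which rose and 3910 fell, against 2999 and 3090 with median-of-ratios scaling and 3115 and 2978 with quantile normalisation. Groups did not overlap at 8162 genes (61.4%, chance 10% for 3 separate libraries per group), and at 8657 with 2 libraries per group (65.1%, chance 33.3%). With 2 libraries per group 1713 genes passed, 520 of which rose and 1193 fell. All had the sign they had with 3, which the position of the libraries left out made nearly certain. An F-test over the 3 groups called 5878 genes, and 749 with 2 libraries per group.

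A last comparison asked whether genes changed with age moved back towards young after GRP-E1F2. Among those with the largest age changes that did, S100a9 of neutrophils fell from 34.6 ± 19.8 TPM in aged to 0.566 ± 0.491 TPM in treated libraries (log2 fold change -4.38, adjusted p = 0.000182, and 0.0183 with 2 libraries per group). S100a8 fell to 1.94 ± 1.68 TPM, Ngp to a listed 0 in every treated library and Camp, the cathelicidin gene, from 3.43 ± 1.23 to 0.254 ± 0.234 TPM. Cox8b fell from 17.7 ± 9.44 to 6.53 ± 1.92 TPM after its rise from 4.35 ± 1.74 TPM. Rpl39l rose back to 38.5 ± 18.4 TPM, and Saa3 rose from 0.125 ± 0.217 to 3.00 ± 2.07 TPM against 2.06 ± 0.794 TPM in young libraries. Scgb1c1 rose from 0.230 ± 0.398 to 1.93 ± 1.15 TPM. In all, 127 of the 2217 genes called with age were called in the opposite direction with GRP-E1F2, 48 that rose and then fell and 79 that fell and then rose. Independent lists of these sizes would share 97.4 and 111. A simulated treated group without effect, with the age effect kept, gave 0 in all 100 draws. Such a group differs from the aged by noise alone, so hardly any gene could pass, and the 0 is no measure for the 127. Leaving out 1 library at a time gave 33 to 217 such genes (33 without aged library 2, 39 and 66 without young libraries 3 and 2, 55 without treated library 3 and 217 without aged library 3). Some settings lay above independent lists: without aged library 2, 14 rose and then fell and 19 fell and then rose against 7.87 and 6.83, and without young library 3, 16 and 23 against 10.02 and 13.2. With no filter it was 129 and 100 against 80.6 and 95.8. Part of such an excess may come from the shared aged libraries.

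Far more genes changed further in the same direction, 723 in number, 169 rising and 554 falling in both comparisons, where independent lists would share 54.5 and 199. The 723 became 120 without aged library 2 and 892 without young library 1, the lowest and highest, and 0 without the 3 in-between libraries. Cerebellar genes fell in both comparisons (medians -0.77 and -3.70). A difference in the regions taken could thus not be told apart from an effect of GRP-E1F2 here. The sign was opposite at 581 of the 2217 genes (26.2%), against 62.5% when a treated group without effect was simulated with the age effect kept, because both comparisons share the aged saline libraries. Across all 13301 genes, which are not independent replicates, the 2 log2 fold changes had a Pearson correlation of 0.24, against a simulated -0.18 with the age effect kept and -0.50 with no effect. The covariance was 0.0341 against a simulated -0.00914, a difference of 0.0433. When 1 library was left out, the correlation ran from 0.12 (without aged library 3) to 0.29 (without young library 1). The covariance ran from 0.0194 to 0.0466 in the same settings. The 3 shared aged libraries cannot be split into parts of 2. Noise in them lowers the covariance, as in the simulated values. The simulation drew noise for each gene separately, from the spread of the main fit, which the in-between libraries may narrow. The simulated values may therefore understate the effect of the shared libraries. With 2 libraries per group 1 of 3 genes called with age, the predicted gene Gm14037, was called in the opposite direction, at 16.0 ± 2.31 TPM in young, a listed 0 in aged and 12.8 ± 2.09 TPM in treated libraries.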

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

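The alternatives were chosen before the data were examined, except the fit of 2 libraries per group and leaving out a library of the group outside a comparison, which were chosen after the result was seen. Without the library of each group that lies between the other pair, the calls dropped to 3 genes with age (1431 at an unadjusted p under 0.05, by limma), 248 with GRP-E1F2, 1713 between treated aged and young and 749 over the 3 groups, and to 1 gene that moved back. Pdyn with age was then 1.78 (adjusted p = 0.412) and Pdyn between treated aged and young 2.37 (adjusted p = 0.0549), with fewer libraries in the fit. Leaving out 1 library at a time gave 371 to 2635 genes with age. That number was 635 without young library 2, 371 without young library 3, 1330 without aged library 1, 379 without aged library 2 and 1172 without treated library 3. Pdyn with age ran from 1.05 to 2.09, and its adjusted p was 0.0621 without young library 2, 0.0969 without young library 3, and 0.0962, 0.114 and 0.0584 without aged libraries 1, 2 and 3, and 0.0652 without treated library 3. Calls with GRP-E1F2 ran from 1345 to 3060, at 1345 without aged library 2 and 1376 without treated library 3, and Pdyn from 0.42 to 0.85 without passing. Calls between treated aged and young ran from 4737 to 6635, Pdyn from 1.68 to 2.72, and calls over the 3 groups from 3971 to 6400. Lists called ran from 14 to 17 with age, from 8 (without aged library 3) to 18 with GRP-E1F2 and from 16 to 19 between treated aged and young. Genes moved back ran from 33 to 217, at 66 without young library 2, 39 without young library 3, 33 without aged library 2, 217 without aged library 3 and 55 without treated library 3. A minimum log2 fold change of 1 left 179, 337 and 1006 genes in the 3 comparisons. With no filter Pdyn with age kept its 1.63 at an adjusted p of 0.0560, over 18383 genes, and 229 genes moved back. In a fit of only the 2 groups compared it had an adjusted p of 0.0548. With the replicate number as a block it stayed at 1.63 (adjusted p = 0.0561), with 2055, 2589 and 5944 genes called; libraries of the same number correlated at -0.055 to 0.13, so the numbers do not pair them. Array weights gave 11859, 12757, 12229 and 13214 calls in the 3 comparisons and for genes differing among the 3 groups, and 5017 genes moved back, made Pdyn with GRP-E1F2 pass at 0.70, and turned Oprk1 with GRP-E1F2 from 0.02 to -0.074. That method weighs libraries near their group mean most, which is where the in-between libraries lie. An estimated correlation left 0, 0 and 0 lists called by camera, against 16, 13 and 17, and fry called 13, 7 and 23. Of the 13 lists that camera called with GRP-E1F2, fry called only the cerebellar (adjusted p = 2.61e-06), myelin (0.0095), astrocyte (0.0123) and reactive astrocyte lists (0.0039), all downward. The opioid (0.109), neurogenesis (0.0538), olfactory bulb (0.107), cholesterol synthesis (0.0849) and immediate early lists (0.226) were among those that did not pass by fry. The cause was not tested for the other changes. Further values of named genes, lists and counts under alternatives numbered 14504. Of these, 13083 stayed on their side of the threshold or, for counts, near the main count. A further 1110 lost the call, 284 gained it and 26 counts moved. Only 1, Oprk1, changed sign with a call in either setting. Changes of sign where neither setting passed were counted among the 13083. Under another scaling 1262 of 1330 stayed in this same sense, 44 lost the call and 24 gained it. Without the 3 in-between libraries only 353 of 665 stayed, 305 lost the call, 1 gained it and 6 counts moved, with fewer libraries in the fit. The 13083 also hold values that passed in neither setting, so their share is no measure of how well the calls held. Depth is unknown, so what it limits could not be shown. Tests on counts were not run.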

Other observations

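The tests of the in-between libraries and of the cerebellar genes were chosen after the result was seen; the tests of shared profiles and of other splits of the samples were set before their results were seen. Some genes passed in lists that camera did not call. Of 13 markers of GABAergic interneurons, 2 rose and 2 fell with GRP-E1F2, Gad2, a GABA-synthesising enzyme, going from 29.0 ± 0.839 to 43.1 ± 11.1 TPM (adjusted p = 0.0475) while Pvalb fell (camera 0.947, median 0.21, mean -0.10). Interferon response genes fell at 5 of 15 with GRP-E1F2 and none rose, without a call of the list (camera 0.122). Antioxidant defence genes fell at 4 of 21 with age and at 10 between treated aged and young. Camera again did not call the list (0.232 and 0.192), while fry called it downward (adjusted p = 0.0478 and 0.00705). Complement genes fell at 2 of 10 with GRP-E1F2, among them C4b from 6.90 ± 1.06 to 4.19 ± 0.857 TPM (adjusted p = 0.0139), with a median of 0.01, a mean of -0.12 and a camera adjusted p of 0.692, downward. Genes of lysosomes and autophagy fell at 8 and rose at 3 of 25 between treated aged and young (camera 0.46, and downward by fry at an adjusted p of 0.00429). Genes of the amyloid and tau list rose at 4 and fell at 5 of 17 (camera 0.916, upward against other genes, median -0.05). In the fit of 2 libraries per group no interferon or complement gene passed with GRP-E1F2, and no antioxidant gene with age. Of the GABAergic markers none rose and 1 fell with GRP-E1F2. Between treated aged and young, 2 antioxidant and 3 lysosomal genes then fell, and 1 amyloid and tau gene rose and 1 fell.

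The extraction protocol names retina. Of the photoreceptor markers, Gngt2 reached 43.0, Rom1 13.6, Pde6g 5.69, Nrl 3.28 and Sag 2.93 TPM at most in any library, and Rlbp1 of other retinal cells 17.2 TPM. Pde6b reached 0.0929 and Gnat1 0.23 TPM, and Pdc and Cnga1 were listed at 0 in all. Among Y-linked genes, Kdm5d and Uty were listed at 0 in all 9 libraries, and of 254 genes placed on chromosome Y 5 were above 0 in any library. Of 14 tested genes of hindbrain patterning and of other hindbrain and cerebellar cells, a list made after the result was seen, 9 fell with age, with a median of -1.72. The Hox genes Hoxb2 and Hoxb3 had means of 3.94 and 4.40 TPM in young and 0.243 and 0.435 TPM in aged libraries.

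In each group 1 library lay between the other pair. The lowest of the 3 observed shares was 95.3%, but arrangements across groups reached 90.9%, so lying between does not exclude a separate animal. A separate animal would show its own share of rarely detected genes, and RNA pooled and sequenced anew was taken to do so too. Of genes listed at 0 in both others, at least 11.5% were above 0 in the 249 other arrangements of 3 libraries. The highest share in these 3 libraries was 1.40%, which argues against a separate animal. It also lay below what was taken for a pool, but no arrangement was known to be a pool sequenced anew and depth is unknown. Pooled RNA is therefore not excluded. Reads taken from the other pair and combined may account for the pattern, since 95.3% or more of genes lay between and the weights were 53.3% to 46.7%, 53.7% to 46.3% and 48.1% to 51.9%. Of genes above 0 in only 1 of the other pair, 58.8%, 59.2% and 57.2% were above 0, so not all reads of both libraries can have been combined, only a part of them. No biological explanation was tested.

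Cerebellar genes were lower in all 3 treated libraries than in any other library, as a mean over the list. A change confined to a single cerebellar cell type would leave the other untouched, but the medians were -3.20 for Purkinje and -3.70 for granule cell genes, which argues against it. A change in 1 type that in turn affected the other was not tested. A lower yield of cerebellum and hindbrain in the treated samples may account for the cerebellar falls. Of 25 genes of other hindbrain and cerebellar cells, 14 were tested, with a median of -0.70 on the log2 scale. Among the 14, none of them on the cerebellar list, 13 were negative and 6 fell. The 6 were Slc6a5, Tfap2b, Tfap2a, Gdf10, Hopx and En1, 4 of them genes of cerebellar interneurons and Bergmann glia. None of 6 Hox genes passed (adjusted p 0.0792 to 0.471), and with aged means of 0.173 to 0.790 TPM they could hardly fall, so a lower yield of hindbrain apart from cerebellum is left open. Of the 6 that fell, Gdf10 of Bergmann glia had means of 39.1, 22.7 and 3.49 TPM and Hopx 1021, 898 and 284 TPM in young, aged and treated libraries. An effect of GRP-E1F2 on all these cells stays open and was not tested apart from the dissection.

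Changes between groups were set against differences between libraries of a single group. The log2 fold changes with GRP-E1F2 correlated across 13301 genes with the difference between young libraries 1 and 2 at r = 0.39 (Spearman 0.50), with no library in common. The treatment changes thus share a profile with a difference inside a single group. Which regions or cells carry it was not tested. The age changes correlated with the difference between treated libraries 1 and 2 at r = 0.0029 (Spearman 0.08), which argues against that profile, over all genes, for age. It cannot exclude a difference in the regions taken, since regions that move apart can cancel. In treated libraries 1 and 2 the striatal list stood at 5.01 and 6.35 and the neocortical list at 6.13 and 5.24, while both were called upward with age. The profile of the treated libraries differs from that of the young libraries (r = -0.0504 between them), whose part in the age changes was not tested. An effect of GRP-E1F2 or of age itself remains open.

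For comparisons of 3 against 3 libraries, 10 splits of the samples are too few for a share under 0.05. The real split was the 1 split of 10 with the most genes for age (2217, highest other 0), GRP-E1F2 (2771 and 0) and treated aged against young (6204 and 0). For lists, 2 of 10 splits gave as many as the real 16 with age (highest other 16), 7 of 10 as many as the 13 with GRP-E1F2 (highest other 26) and 4 of 10 as many as the 17 between treated aged and young (highest other 20). Among each 100 drawn splits of the 9 libraries, only the real 1 reached 5878 genes over the 3 groups (highest other 1995) and 127 genes moved back (highest other 1). Other splits part the in-between libraries from the other pair, which widens the spread within groups, so these splits cannot show whether chance is excluded.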
